A study of Mus musculus with 6 samples.

How the data were processed

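RNA was sequenced from 6 samples of mouse CD49f-positive epidermal cells. CD49f is integrin alpha 6, a surface protein of basal keratinocytes, and the cells were sorted by flow cytometry from suspensions of skin, per the labels' protocols. All samples carried floxed Rnaseh2b alleles, and 3 of them also carried K14-Cre, a recombinase driven by the keratin 14 promoter of basal keratinocytes. RNA was extracted on columns and libraries were made with a directional mRNA kit, per the labels' protocols. Nothing in the labels says whether the replicates are separate animals, so the p-values of single genes measure the spread between these samples, part of which may be technical. Both sexes were found within each group, so each group held more than 1 animal.

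The authors deposited raw read counts per gene for each library, with no normalization, per the file headers. Reads were aligned with GSNAP and counted with featureCounts on the mouse build mm10, per the submitters' processing notes. Tool versions, the strand setting and the handling of reads shared between overlapping or near-identical genes are not given in the sources used here. Without a strand setting, reads of a gene and of an antisense partner cannot be told apart where their exons overlap. A partner is named beside a reported gene if it covers at least 5% of the exon length and had a mean of at least 10 counts; smaller overlaps are not named. The table held 38924 genes, of which 37607 were matched to a symbol by their identifier, and 146 of the tested genes had none. Of the tested genes, 15380 were found in the GENCODE annotation of the same build, and 15379 of these lay on the same chromosome there.

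Library totals ran from 22948779 to 31718094 counts. CPM values are counts scaled to the total over the tested genes times the scaling factor of the library (below). A floor of 3 counts corresponded to between 0.0922 and 0.143 CPM, and this floor covers counting error only. Genes were kept by filterByExpr with its minimum count of 10, which left 15525. Counts were scaled by the trimmed mean of M values (TMM) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. No covariate was used. Fold changes are Cre-positive minus Cre-negative on the log2 scale, standard errors (SE) come from the same test, and CPM values are given as mean ± SD over 3 libraries. The common biological coefficient of variation was 0.172.

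The tests, the alternatives and 27 gene lists were chosen before the data were examined. The lists covered p53 target genes, interferon-stimulated genes, nucleic acid sensing and nucleases, RNase H and ribonucleotide excision repair, DNA double-strand break and crosslink repair, replication, mitosis, keratinocyte layers and wound keratinocytes, hair follicle and hair shaft, sebaceous gland, keratinocyte cytokines, T cells, myeloid cells, fibroblasts, endothelial cells, melanocytes and Schwann cells, muscle and blood, immediate early genes, mitochondrially encoded genes, oxidative stress, the unfolded protein response, apoptosis, senescence-associated and carcinoma-associated genes, and cholesterol biosynthesis. Each list was tested with camera from limma 3.58.1, which sets its members against all other genes, with the correlation between genes preset at 0.01 and adjustment over the lists. With a preset correlation its p-values rest mainly on the spread between genes and do not measure that between samples. Camera with a correlation estimated from the data, and fry, were run beside it.

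The genes named were Rnaseh2b, Rnaseh2a, Rnaseh2c and Rnaseh1; the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM, no overlap between the groups and a symbol other than a gene model; up to 4 members of each list with the smallest adjusted p; and Trp53 with the most abundant marker of each other cell type. Genes named outside this rule are said to be so. Some genes that the rule takes are not reported here.

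Alternatives were DESeq2 size factors, scaling by total count alone, the Wald test of DESeq2 1.42.0, limma-voom, no filter beyond 1 count, a minimum mean of 1 CPM, a test against a 1.5-fold change, and leaving out each library in turn. Sex, read from Xist and Y-linked genes, was added as a covariate after the data had been seen. The fits were tested on simulated counts for the 15525 genes of the Cre comparison, with 200 genes changed. There edgeR recovered 22.4% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 78.8% of those changed 4-fold, and 9 of its 123 calls were unchanged genes. DESeq2 recovered 37.3%, 80.6% and 83.3%, with 49 unchanged genes among 183 calls. Limma-voom recovered 22.4%, 68.7% and 78.8%, with 8 unchanged genes among 121 calls.

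Counts were compared between libraries of each group to look for a library present more than once. The chi-square per degree of freedom was 8.70 to 63.7 within groups, far above sampling noise, so each library was counted as 1 sample.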

Results

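Gene expression was measured by RNA sequencing in CD49f-positive epidermal cells of mice with floxed Rnaseh2b alleles. The 3 K14-Cre-positive libraries held 31718094, 23186065 and 23807449 counts and the 3 K14-Cre-negative libraries 24340191, 22948779 and 25362538. The comparison asks how the transcriptome of these cells differs when the Cre that deletes the floxed gene in keratinocytes is present. Rnaseh2b encodes a subunit of RNase H2, the enzyme that starts the removal of ribonucleotides from DNA.

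Rnaseh2b mRNA fell to 19.6% of the Cre-negative mean in Cre-positive cells, from 21.4 ± 0.599 to 4.18 ± 1.02 CPM (SD, n = 3 each). Of 37 genes tested that are known as targets of the tumour suppressor p53, 12 rose, among them Ddit4l, Eda2r, Ccng1 and Polk, and 25 did not pass the threshold. Pigment-cell genes such as Tyrp1, Mlana and Dct rose as well, and so did the immediate early gene Fos. The antigen-presentation gene H2-Ab1 fell while Lyz2, the lysozyme gene of phagocytes, rose. By the quasi-likelihood test of edgeR, 63 genes rose and 17 fell among 15525 tested, and 2913 had an unadjusted p under 0.05.

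Rnaseh2b (ENSMUSG00000021932) lies on chromosome 14 from 62292589 to 62372992 on the plus strand of mm10, and its counted exons form 11 separate blocks. Its counts were 172, 90 and 69 in the Cre-positive libraries against 543, 504 and 570 in the Cre-negative ones, which matches the labels. The log2 fold change was -2.34 (SE 0.17, edgeR adjusted p = 0.0102). It stayed between -2.55 and -2.19 when any 1 library was left out, and the call ended without Cre-positive replicate 2 (edgeR adjusted p = 0.0508) or Cre-negative replicate 1, 2 or 3 (0.124, 0.0841 and 0.103). Counts were given per gene and not per exon, so reads from exons outside the floxed part are included. The other RNase H genes did not pass the threshold. Rnaseh2a and Rnaseh2c, which encode the remaining subunits of RNase H2, had log2 fold changes of -0.12 (SE 0.10) and -0.05 (SE 0.12). Rnaseh1, which encodes a separate RNase H, had 0.08 (SE 0.09), and this sign turned under scaling by total count (-0.034). On the opposite strand, Kat5 covers 29.1% of the exon length of Rnaseh2c and Prdx2 5.04% of that of Rnaseh2a.

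All 80 genes past the threshold had no overlap between the groups; over all tested genes this held for 28.0%, where chance gives 10%. The largest rise was that of Gria3, a glutamate receptor subunit gene, from 0.415 ± 0.338 to 6.95 ± 3.18 CPM (log2 fold change 4.04, SE 0.61, edgeR adjusted p = 0.0485; 4.94 without Cre-negative replicate 3). Abcb1b, which encodes a multidrug efflux pump, had the smallest adjusted p (0.00183) and rose from 1.99 ± 0.195 to 21.1 ± 3.45 CPM. Other large rises on the log2 scale were those of Ddit4l (3.68), Gapdhs (3.38), Abhd11os (3.24), the axon guidance gene Slit1 (2.57), the ectodysplasin A2 receptor gene Eda2r (2.52), Cpt1c (2.49), Igsf9b (2.33) and the phosphatase gene Ptp4a3 (2.08). Gapdhs shares 10.1% of its exon length with Tmem147os on the opposite strand, and Abhd11os shares 8.84% with Abhd11. Abhd11os lay at 0.241, 0.246 and 0.152 CPM in Cre-negative replicates 1, 2 and 3, near the floor of 3 counts, so the size of its fold is uncertain. After Rnaseh2b, the largest fall was that of the class II histocompatibility gene H2-Ab1, from 17.1 ± 6.10 to 3.48 ± 1.14 CPM (log2 fold change -2.29, SE 0.32, edgeR adjusted p = 0.0400). The others were Tmtc1 (-1.46), Plppr3 (-0.98), the cadherin gene Cdh4 (-0.97), the kinase gene Wnk4 (-0.94), the chemokine receptor gene Cxcr4 (-0.83), Brinp1 (-0.81), the acetyl-CoA carboxylase gene Acacb (-0.75) and Arhgef19 (-0.73). Ptbp1 on the opposite strand covers 5.76% of the exon length of Plppr3. In limma-voom the calls ended for Gria3 (adjusted p = 0.0770), Abhd11os (0.0731), Eda2r (0.0614), H2-Ab1 (0.0566) and Brinp1 (0.0507).

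Of 37 p53 target genes tested, 12 rose, 0 fell and 25 did not pass the threshold, and 27 rose when adjusted over the list alone. Ccng1, which encodes cyclin G1, rose from 25.9 ± 1.57 to 81.6 ± 18.8 CPM (log2 fold change 1.65, SE 0.17, edgeR adjusted p = 0.0181). Polk, which encodes a translesion DNA polymerase, rose by 1.49 (SE 0.13), and Phlda3 and Def6 rose by 0.75 and 0.76 on the log2 scale. Outside the naming rule, and chosen after their values were seen, Cdkn1a, the cell cycle inhibitor p21, had a log2 fold change of 0.44 (SE 0.13, edgeR adjusted p = 0.163) and Mdm2, the ubiquitin ligase of p53, had a log2 fold change of 0.54 (edgeR adjusted p = 0.0640). Trp53 itself had a log2 fold change of -0.25 (SE 0.08, edgeR adjusted p = 0.196). The list stood above all other genes by camera (adjusted p = 5.74e-42), and did so with an estimated correlation (adjusted p = 0.0267). By edgeR, 5, 1 and 24 members rose without Cre-positive replicate 1, 2 or 3, and 0 without any 1 of the Cre-negative libraries.

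**Figure D1:**
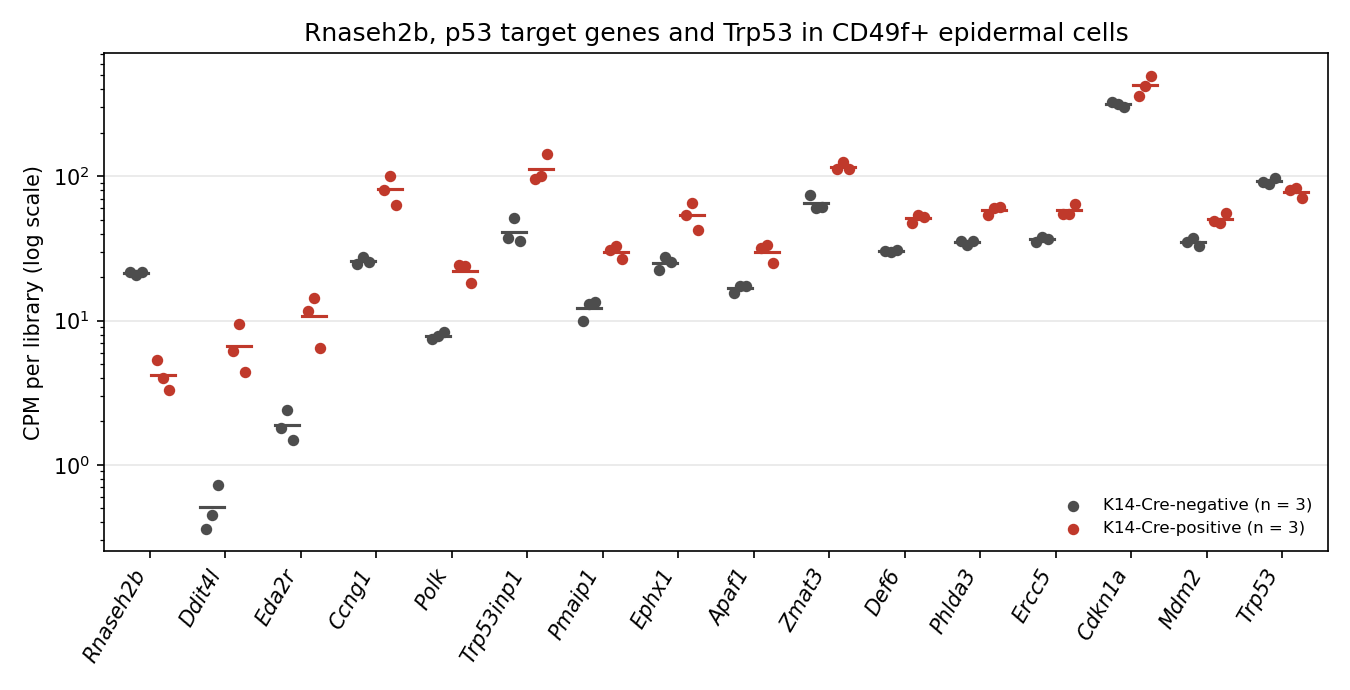
CPM per library on a log axis for Rnaseh2b, the 12 p53 target genes past the threshold, Cdkn1a, Mdm2 and Trp53; points are libraries, 3 per group, and short lines are group means. Ddit4l lies at a mean of 0.512 CPM in the Cre-negative and 6.66 CPM in the Cre-positive libraries, and Rnaseh2b goes the other way.

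Of 13 melanocyte and Schwann cell genes, 7 rose, 0 fell and 6 did not pass the threshold, with 9 higher when adjusted over the list alone. Tyrp1, an enzyme gene of melanin synthesis, rose from 15.5 ± 0.895 to 42.2 ± 4.06 CPM (log2 fold change 1.45, SE 0.10, edgeR adjusted p = 0.00938). Mlana, a melanosome gene, rose by 1.57 (SE 0.15), and Kit, the stem cell factor receptor gene, by 0.80 (SE 0.09). Dct, the most abundant marker of the list, rose from 204 ± 12.5 to 359 ± 35.1 CPM. The camera adjusted p was 1.60e-24, and with an estimated correlation the adjusted p was 0.0267. That call was lost when sex was a covariate as well (adjusted p = 0.111), as it was for the p53 target genes. By edgeR, 2, 1 and 8 members rose without Cre-positive replicate 1, 2 or 3, and 0 without any 1 of the Cre-negative libraries. These and the p53 target genes were the 2 lists of 27 called with an estimated correlation, against 17 with the preset one.

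The myeloid list moved both ways: of 18 members 1 rose, 1 fell and 16 did not pass the threshold, with 5 higher and 3 lower when adjusted over the list alone. DESeq2 called 3 higher and 3 lower, and limma-voom 1 higher and 0 lower, with 9 at an unadjusted p under 0.05 by edgeR. Lyz2 rose from 5.91 ± 0.797 to 14.8 ± 2.55 CPM (log2 fold change 1.33, SE 0.17, edgeR adjusted p = 0.0368). Besides H2-Ab1, the class II genes Cd74 and H2-Aa had log2 fold changes of -2.42 (edgeR adjusted p = 0.0572) and -2.52 (edgeR adjusted p = 0.0670). Among members named after their values were seen, the phagocyte genes Mpeg1, Cd68 and Adgre1 and the cathepsin gene Ctss had 1.0, 0.49, 0.62 and 0.37, higher when adjusted over the list alone (adjusted p = 0.00356, 0.0134, 0.0349 and 0.0383). The others are the remaining class II gene, H2-Eb1, at -0.22 (SE 0.43, edgeR adjusted p = 0.812), and Tyrobp, Fcer1g and Csf1r, genes of phagocytes and other myeloid cells, at -0.08, -0.07 and -0.04. Hmgxb3 on the opposite strand covers 17.8% of the exon length of Csf1r. Epcam, the most abundant member, is also expressed by epithelial cells and had -0.11. The list's median was -0.02 and its mean -0.17, whereas camera gave the direction up without passing the threshold (adjusted p = 0.809). Cd207, the langerin gene of Langerhans cells, was below the count filter, with 2, 6 and 0 counts in Cre-positive and 16, 9 and 9 in Cre-negative libraries.

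**Figure D2:**
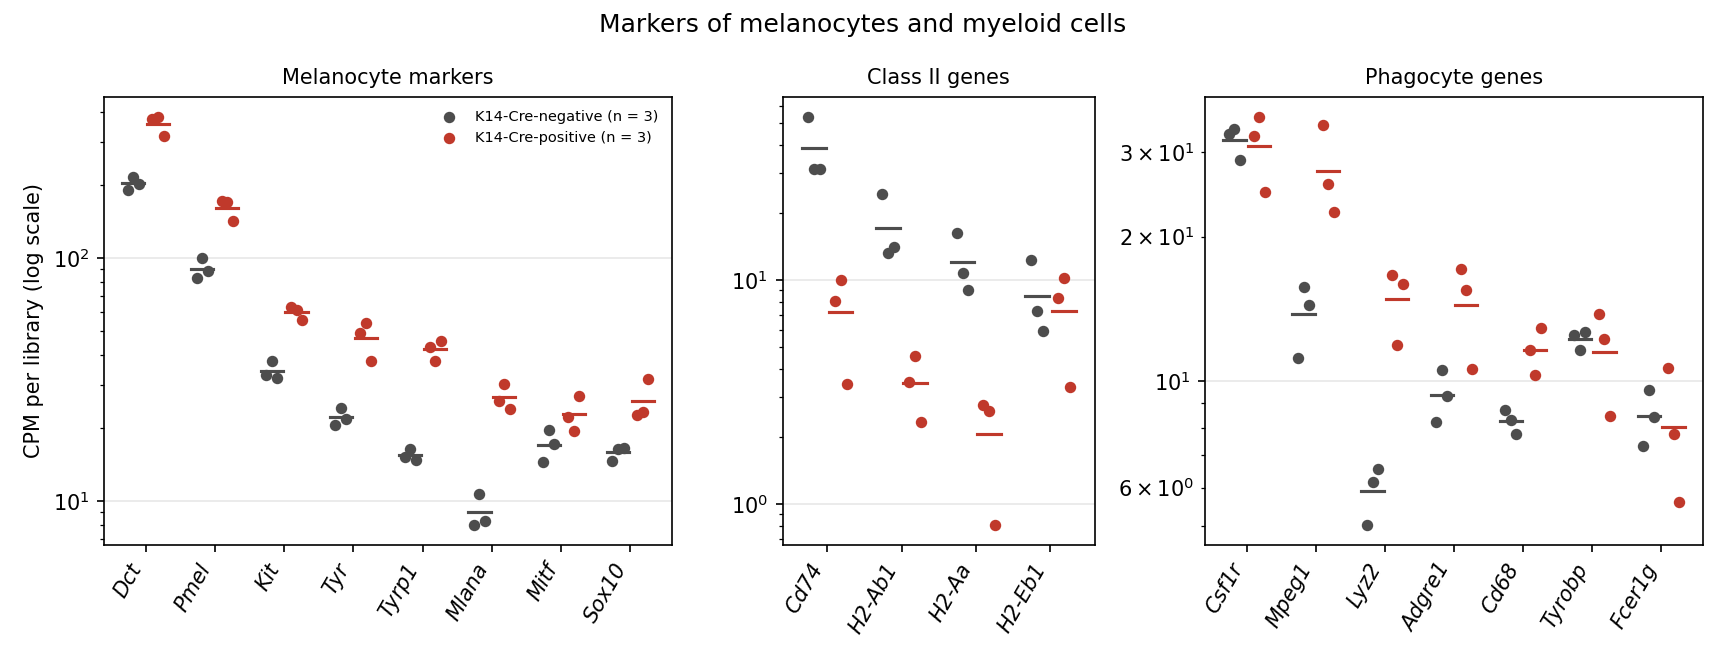
CPM per library on log axes, 1 per panel, for melanocyte markers, class II genes and phagocyte genes; points are libraries, 3 per group, and short lines are group means. Dct has a mean of 359 CPM in Cre-positive and 204 CPM in Cre-negative libraries, and Cd74 has 7.18 against 38.7 CPM, whereas H2-Eb1 has 7.28 against 8.49 CPM.

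Where edgeR called members of a list, DESeq2 and limma-voom called 25 and 9 higher of the p53 target genes, 8 and 7 of the melanocyte and Schwann cell genes, 11 and 2 of the immediate early genes and 3 and 1 of the oxidative stress genes. In the lists below where edgeR called no member, limma-voom called 0 as well, and the counts at an unadjusted p under 0.05 and by DESeq2 are given with each. For T cells, 0 of 12 genes rose or fell by edgeR, with 8 at an unadjusted p under 0.05, 2 by DESeq2 and 8 lower when adjusted over the list alone. Cd3g and Cd3e, which encode chains of the T cell receptor complex, had log2 fold changes of -1.11 (SE 0.24) and -0.78 (SE 0.18), and the cytotoxic granule gene Nkg7 had -1.17. Thy1, the most abundant marker and also expressed by fibroblasts, had -0.07, and its sign turned with sex as a covariate. Camera placed the list lower (adjusted p = 1.25e-05), which was lost with an estimated correlation (adjusted p = 0.315). Of 15 fibroblast genes none passed by edgeR, 1 at an unadjusted p under 0.05, 1 by DESeq2 and 0 when adjusted over the list alone, and neither test of the list passed (camera adjusted p = 0.990). The mean log2 CPM of this list lay 1.26 above the Cre-negative mean in Cre-positive replicate 1 and at -1.42 and -0.76 in replicates 2 and 3, and camera called it without replicate 1 (adjusted p = 0.000580). Vim, the vimentin gene, which many other cell types also express, had 0.60 (SE 0.14), while Col1a1, a collagen gene, had 143 ± 219 against 79.4 ± 91.7 CPM, and its sign turned in limma-voom and without Cre-positive replicate 1. The 10 endothelial genes had 0 past the threshold by edgeR, 0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 when adjusted over the list alone (camera adjusted p = 0.685), with Kdr, a receptor gene for vascular endothelial growth factor, at -0.67 (SE 0.84) and Cldn5 at -1.82 (SE 1.14). This list lay at 1.24, -1.38 and -1.10 in Cre-positive replicates 1, 2 and 3, and was likewise called without replicate 1 (adjusted p = 0.00453). Without it Kdr had -2.33 and Cldn5 -4.08, and Cldn5 had -0.92 without Cre-negative replicate 3. The Cre-negative libraries themselves ranged from -0.77 to 0.89 for the fibroblast list, from -1.15 to 1.18 for the endothelial list and from -0.84 to 0.83 for the muscle and blood list. Among 13 muscle and blood genes 0 passed by edgeR, 3 at an unadjusted p under 0.05, 0 by DESeq2 and 0 when adjusted over the list alone. The globin genes Hbb-bs and Hba-a2 had -0.65 and -0.61, and the list's camera call (adjusted p = 0.00332) was lost with an estimated correlation (adjusted p = 0.568) and without Cre-negative replicate 3 (adjusted p = 0.195).

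Immediate early and dissociation genes held 3 that rose, 0 that fell and 20 not past the threshold, and 13 rose when adjusted over the list alone. Fos, a subunit gene of the transcription factor AP-1, rose from 93.1 ± 15.0 to 216 ± 11.3 CPM (log2 fold change 1.21, SE 0.12, edgeR adjusted p = 0.0181). Ier2 rose by 0.55 (SE 0.07) and Zfp36, which promotes decay of cytokine mRNA, by 0.86 (SE 0.13), a call that ended in limma-voom (adjusted p = 0.0508). The camera call (adjusted p = 1.97e-11) was lost with an estimated correlation (adjusted p = 0.315). Of 16 oxidative stress genes, 1 rose, 0 fell and 15 did not pass the threshold, with 2 higher when adjusted over the list alone. Slc7a11, the cystine transporter gene, rose by 0.96 (SE 0.13, edgeR adjusted p = 0.0378), and the sulfiredoxin gene Srxn1 had 1.35 (edgeR adjusted p = 0.0971). The list itself was not called (camera adjusted p = 0.0824), but was without Cre-positive replicate 1 or 3 (adjusted p = 0.0365 and 0.00760) and under total count scaling (adjusted p = 0.0477).

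Cholesterol biosynthesis genes had positive log2 fold changes in 18 of 18 members, yet 0 passed by edgeR, 12 at an unadjusted p under 0.05 and 8 by DESeq2, and 11 rose when adjusted over the list alone. Insig1, a regulator of sterol synthesis, had 0.54 (SE 0.09) and the sterol desaturase gene Sc5d 0.62 (SE 0.13). The camera call (adjusted p = 1.50e-09) was lost with an estimated correlation (adjusted p = 0.317). For the unfolded protein and integrated stress response, 0 of 16 passed by edgeR, 2 at an unadjusted p under 0.05, 2 by DESeq2 and 2 when adjusted over the list alone, both higher. Slc7a5, an amino acid transporter gene, had 0.43 (SE 0.07) and Sesn2, which is also in the p53 target list, 0.66 (SE 0.13). Camera (adjusted p = 0.0490) lost its call with an estimated correlation (adjusted p = 0.568). It also lost it without Cre-positive replicate 2 or 3 (adjusted p = 0.182 and 0.0614) or Cre-negative replicate 2 (adjusted p = 0.363), under total count scaling (adjusted p = 0.0849) and at a minimum mean of 1 CPM (adjusted p = 0.0578). The apoptosis list had 0 of 15 past the threshold by edgeR, 4 at an unadjusted p under 0.05, 0 by DESeq2 and 0 when adjusted over the list alone (camera adjusted p = 0.694), with Bcl2l11, which encodes the pro-apoptotic protein BIM, at 0.53 and Bcl2 at -0.27. It leaves out apoptosis genes held in the p53 list. Outside the naming rule, Pmaip1 and Apaf1 of that list rose by 1.31 and 0.84 (edgeR adjusted p = 0.0191 and 0.0445), while its members Bax, Bbc3 and Fas did not pass. With sex as a covariate, Fas had 1.38 (SE 0.26), Bbc3 0.66 (SE 0.13) and Bax 0.20 (SE 0.16), against 1.23 for Pmaip1 and 0.76 for Apaf1. For Fas and Bbc3, not passing the threshold therefore does not mean no change. Of 18 senescence-associated and carcinoma-associated genes 0 passed by edgeR, 3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 when adjusted over the list alone (camera adjusted p = 0.685). Plaur, the urokinase receptor gene, had 0.80 and the collagenase gene Mmp13 0.64.

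Genes of RNase H and ribonucleotide excision repair held 1 that fell, Rnaseh2b, 0 that rose and 11 not past the threshold, and 1 fell when adjusted over the list alone. Pold1, which encodes the catalytic subunit of DNA polymerase delta, had -0.44 (SE 0.12) and the DNA ligase gene Lig1 -0.44 (SE 0.18), and the camera call (adjusted p = 7.97e-05) was lost with an estimated correlation (adjusted p = 0.317). The targeted gene Rnaseh2b counts toward that call, and the list was not tested without it. The list's mean log2 fold change was -0.34 and its median -0.14. Zswim9 on the opposite strand covers 5.79% of the exon length of Lig1. Replication genes had negative log2 fold changes in 26 of 26 members, with 0 past the threshold by edgeR, 5 at an unadjusted p under 0.05, 0 by DESeq2 and 0 when adjusted over the list alone. Pola1, which encodes the catalytic subunit of DNA polymerase alpha, had -0.50 (SE 0.17), the helicase subunit gene Mcm6 -0.35 (SE 0.13) and Gins2 -0.56, a gene covered over 67.3% of its exon length by Gse1 on the opposite strand. Their mean log2 CPM lay 0.80 below the Cre-negative mean in Cre-positive replicate 3, against -0.10 and -0.09 in replicates 1 and 2, and camera (adjusted p = 9.17e-06) lost its call with an estimated correlation (adjusted p = 0.581). Mitosis genes had 0 of 27 past the threshold by edgeR, 0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 when adjusted over the list alone. Bub1b, a spindle checkpoint gene, had -0.44 (SE 0.23) and the proliferation marker Mki67 -0.32 (SE 0.25). This list differed from the Cre-negative mean by -0.82 in replicate 3 and by 0.01 and 0.15 in the other Cre-positive libraries, and its camera call (adjusted p = 0.0222), lost with an estimated correlation (adjusted p = 0.816), turned direction without replicate 3 (adjusted p = 0.0616). The mitosis call also ended without Cre-negative replicate 3 (adjusted p = 0.0938) and under total count scaling (adjusted p = 0.0867). Of 27 genes of double-strand break and crosslink repair 0 passed by edgeR, 4 at an unadjusted p under 0.05, 2 by DESeq2 and 0 when adjusted over the list alone. Parp1, a sensor of DNA breaks, had -0.37 (SE 0.10) and the Fanconi anaemia gene Fancb 0.39 (SE 0.09), with camera (adjusted p = 0.0236) losing its call with an estimated correlation (adjusted p = 0.770). Their mean log2 CPM differed from the Cre-negative mean by -0.57 in Cre-positive replicate 3 and by 0.0031 and 0.0057 in replicates 1 and 2. The call ended without that replicate 3 (adjusted p = 0.988), without Cre-negative replicate 1 (adjusted p = 0.0807) and under total count scaling (adjusted p = 0.0584).

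Among 15 basal keratinocyte genes 0 passed by edgeR, 3 at an unadjusted p under 0.05 and 2 by DESeq2, with 1 higher and 1 lower when adjusted over the list alone. Krt15, a keratin of basal and bulge cells, had 1034 ± 175 against 1957 ± 217 CPM (log2 fold change -0.92, edgeR adjusted p = 0.0572) and Itgb4, a hemidesmosome integrin gene, 0.50 (SE 0.10), and the list was not called (camera adjusted p = 0.685). Suprabasal and cornified genes had 0 of 24 past the threshold by edgeR, 14 at an unadjusted p under 0.05 and 6 by DESeq2, with 2 higher and 1 lower when adjusted over the list alone. The desmosome gene Dsc1 had 0.84 (SE 0.18) and the protease inhibitor gene Spink5 0.71 (SE 0.17), while Krt2, a keratin of suprabasal cells, had -5.51 (SE 1.22, edgeR adjusted p = 0.104). Krt2 lay at 0.461, 0.221 and 0.143 CPM in Cre-positive replicates 1, 2 and 3, the last of these at the floor of 3 counts, and at 10.5, 1.11 and 29.3 CPM in the Cre-negative ones, and had -4.01 (SE 1.22) with sex as a covariate, -4.30 without Cre-negative replicate 3 and -6.18 without Cre-positive replicate 1. The list's mean log2 CPM lay 0.57 above the Cre-negative mean in Cre-positive replicate 3 and at -0.01 and 0.12 in the others, and camera (adjusted p = 1.98e-06) lost its call with an estimated correlation (adjusted p = 0.497). For hyperproliferation and wound genes, 0 of 22 passed by edgeR, 10 at an unadjusted p under 0.05 and 9 by DESeq2, with 9 higher and 1 lower when adjusted over the list alone. The wound keratin genes Krt16 and Krt6b had 1.13 (SE 0.20, edgeR adjusted p = 0.0755) and 1.29 (SE 0.27), and the cornified envelope gene Sprr1b 2.30 (SE 0.53). Sprr1b lay at 289, 300.3 and 1034 CPM in Cre-positive replicates 1, 2 and 3 against 110.2 ± 33.3 CPM, and had 1.42 without replicate 3 (edgeR adjusted p = 0.0213). The list's mean log2 CPM lay 1.0 above the Cre-negative mean in that replicate, against 0.52 and 0.39 in the others. Their camera call (adjusted p = 6.37e-06) was lost with an estimated correlation (adjusted p = 0.317).

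Hair follicle genes had 0 of 16 past the threshold by edgeR, 6 at an unadjusted p under 0.05, 2 by DESeq2 and 2 lower when adjusted over the list alone. Lrig1, a stem cell marker of the upper follicle, had -0.41 (SE 0.08), the bulge transcription factor gene Sox9 -0.44 (SE 0.10) and Krt79, the most abundant marker, -0.30, and camera (adjusted p = 0.000788) lost its call with an estimated correlation (adjusted p = 0.446). The list lay at 0.10, -0.32 and -0.55 in Cre-positive replicates 1, 2 and 3. Hair shaft and inner root sheath genes were negative in 17 of 17 members, with 0 past the threshold by edgeR, 6 at an unadjusted p under 0.05, 2 by DESeq2 and 0 when adjusted over the list alone. The inner root sheath keratin gene Krt71 had -0.65 (SE 0.21), the hair keratin gene Krt35 -0.77 (SE 0.24) and Tchh, the trichohyalin gene, -0.35, and the camera call (adjusted p = 1.72e-05) was lost with an estimated correlation (adjusted p = 0.505). Relative to the Cre-negative mean, this list lay at 0.43 in Cre-negative replicate 2 and at -0.23 and -0.20 in Cre-negative replicates 1 and 3, against -0.19, -0.44 and -0.59 in Cre-positive replicates 1, 2 and 3. In the sebaceous gland list 0 of 14 passed by edgeR, 7 at an unadjusted p under 0.05 and 3 by DESeq2, and 6 fell when adjusted over the list alone. Soat1, a cholesterol esterification enzyme gene, had -0.86 (SE 0.14), the fatty acid elongase gene Elovl3 -0.80 (SE 0.22) and Dgat2, the most abundant marker, 0.45, and camera (adjusted p = 0.00577) lost its call with an estimated correlation (adjusted p = 0.317).

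Interferon-stimulated genes had positive log2 fold changes in 33 of 39 members, with 0 past the threshold by edgeR, 10 at an unadjusted p under 0.05, 7 by DESeq2 and 0 when adjusted over the list alone. Ddx58, which encodes the RNA sensor RIG-I, had 0.74 (SE 0.17, edgeR adjusted p = 0.118) and Eif2ak2, which encodes the kinase PKR, 0.49 (SE 0.12). The list's mean log2 CPM lay 0.80 above the Cre-negative mean in Cre-positive replicate 1 and 0.11 and 0.03 above it in replicates 2 and 3. The camera call (adjusted p = 0.000132) was lost with an estimated correlation (adjusted p = 0.630) and without Cre-positive replicate 1 (adjusted p = 0.225). Nucleic acid sensing and nuclease genes had 0 of 17 past the threshold by edgeR, 5 at an unadjusted p under 0.05, 3 by DESeq2 and 0 when adjusted over the list alone (camera adjusted p = 0.0705, and 0.0179 without Cre-positive replicate 2), with the DNase gene Dnase1l3 at 0.87 (SE 0.25) and the RNA editing enzyme gene Adar at 0.31 (SE 0.09). Of 15 keratinocyte cytokine and chemokine genes 0 passed by edgeR, 3 at an unadjusted p under 0.05 and 3 by DESeq2, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.322). The skin chemokine gene Ccl27a had -0.62 (SE 0.13) and Il1rn, the interleukin-1 receptor antagonist gene, 0.41 (SE 0.10). The 9 mitochondrially encoded genes had 0 past the threshold by edgeR, 0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 when adjusted over the list alone (camera adjusted p = 0.694), with mt-Cytb at -0.08 and mt-Nd6 at 0.15.

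**Figure D3:**
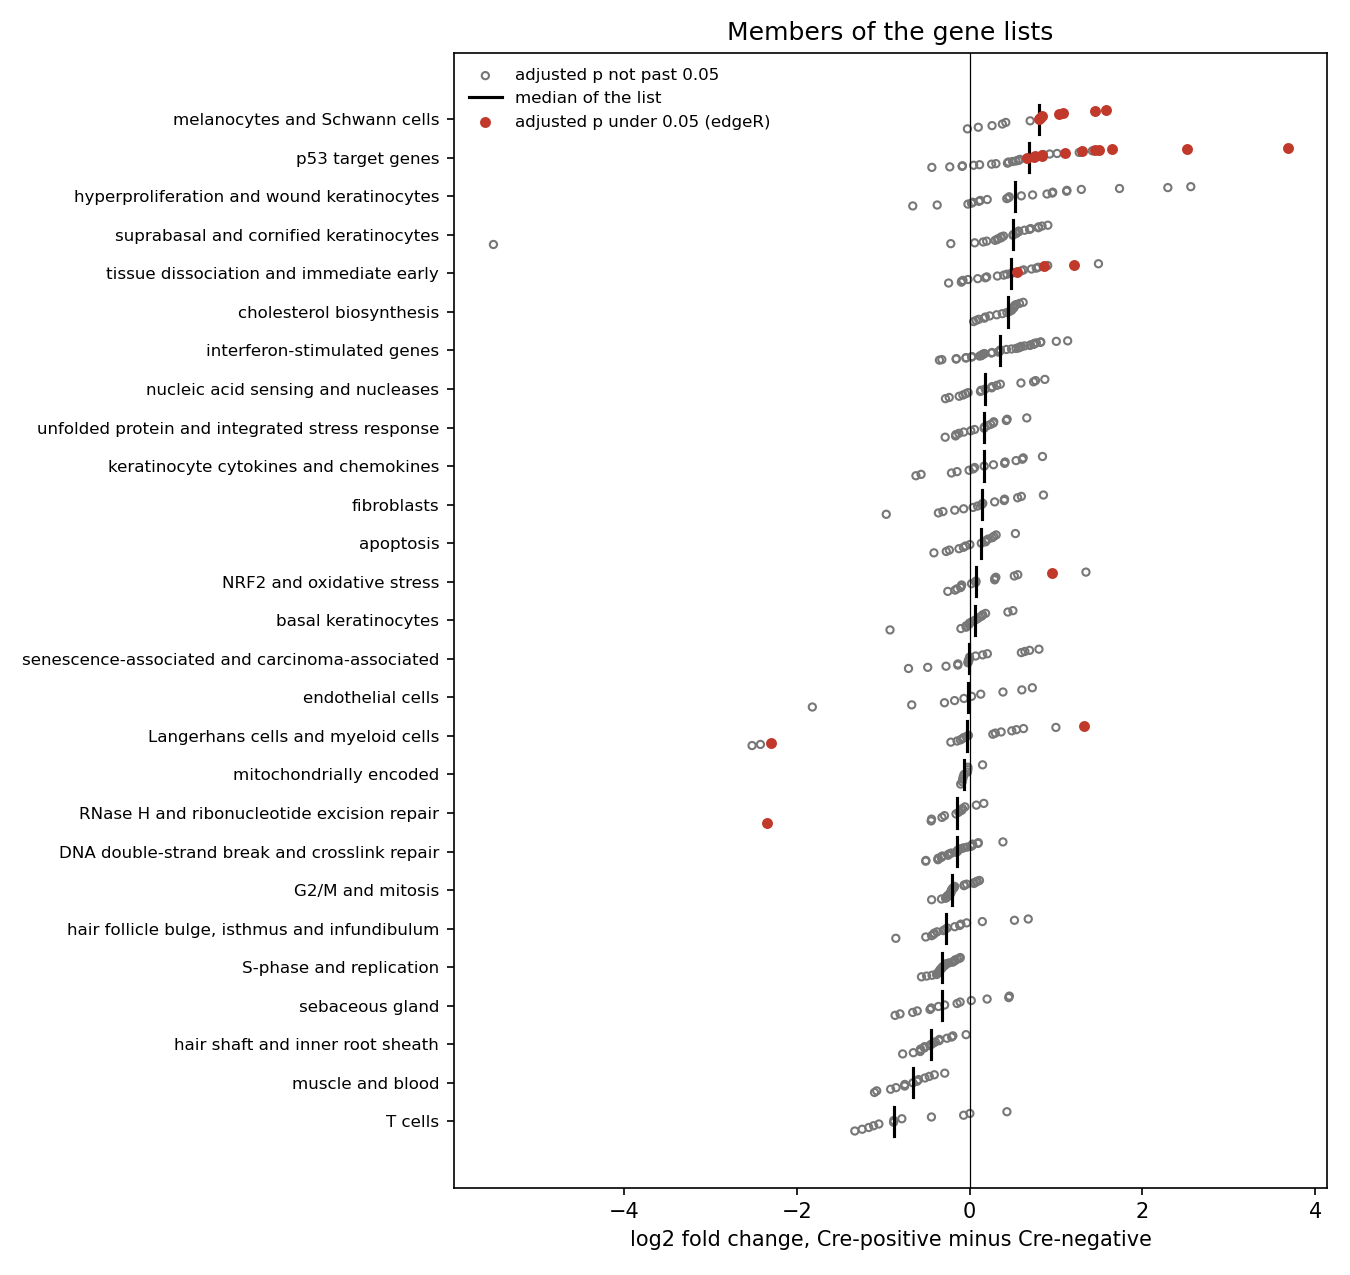
Log2 fold changes (Cre-positive minus Cre-negative, horizontal axis) of the tested members of the 27 gene lists, 1 list per row ordered by its median; filled points passed the edgeR threshold, open points did not, and vertical lines are medians. The melanocyte and p53 lists lie at the top with medians of 0.80 and 0.69, and T cells at the bottom with -0.88.

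Xist and Y-linked genes showed 1 female and 2 male libraries in the Cre-positive group and 2 female and 1 male in the Cre-negative group, which the labels do not give. The female Cre-positive library was replicate 3 and the male Cre-negative library was replicate 2, so leaving out either left its group with 1 sex. Within the Cre-positive group, sex cannot be told apart from other traits of replicate 3. With sex as a covariate, chosen after seeing the data, 34 genes rose and 8 fell by edgeR, 7 of them risen p53 target genes. Counts of calls depended on single libraries: leaving out Cre-positive replicate 3, which stood apart on the first principal component (41.9% of the variance), gave 288 higher and 134 lower, leaving out Cre-positive replicate 1 gave 20 and 5, and replicate 2 gave 7 and 0. Without Cre-negative replicate 1, 2 or 3 the totals were 0, 0 and 1, with 1844, 2085 and 1680 genes at an unadjusted p under 0.05 and all 80 genes in their original direction. That direction was largely fixed in advance, since these 80 genes had no overlap between the groups.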

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

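All settings were chosen beforehand except sex as a covariate, added after seeing the data, and the counts for p53 and melanocyte genes. Genes higher (63) and lower (17) became 27 and 14 under total count scaling, which shifted the median of all genes by -0.11 and the share of higher calls from 78.8% to 65.9%; 527 and 277 with DESeq2; 104 and 38 without a filter; 2 and 1 against a 1.5-fold change; and 34 and 8 with sex. Leaving out 1 library gave 0 to 288 higher and 0 to 134 lower (288 and 134 without Cre-positive replicate 3), with fewer samples in each fit. The 80 genes kept their direction in every setting, except that 1 was not tested at a minimum mean of 1 CPM. Where 1 library was left out this was largely fixed in advance, since none of the 80 overlapped between the groups. The p53 genes higher (12) became 6 with total counts, 25 with DESeq2, 19 without a filter, 0 against a 1.5-fold change, 7 with sex and 0 to 24 without 1 library. The melanocyte genes higher (7) became 2 with total counts, 1 against a 1.5-fold change and 0 to 8 without 1 library. Lists called (17) became 2 with an estimated correlation, 2 with fry and 0 with sex and an estimated correlation, and 15 to 19 without 1 library. Without 1 library Rnaseh2b ranged from -2.55 to -2.19, and its call ended without Cre-positive replicate 2 (adjusted p = 0.0508) or Cre-negative replicate 1 (0.124), 2 (0.0841) or 3 (0.103). Signs turned, all short of the threshold, for Col1a1 in limma-voom (-0.013), Dcn (-0.024) and Rnaseh1 (-0.034) with total counts, and Eng (-0.087), Rnaseh2c (0.020) and Thy1 (0.044) with sex. Without 1 library the range crossed 0 for Col1a1 (-2.27 to 2.43), Dcn (-0.0053 to 0.25), Eng (-0.48 to 0.40), mt-Nd4 (-0.13 to 0.011), Rnaseh2c (-0.17 to 0.039), Tek (-0.95 to 1.69) and Thy1 (-0.34 to 0.14). The mitosis list had an adjusted p of 3.28e-06 to 0.0938 and turned direction without Cre-positive replicate 3 (0.0616). Where the construction does not show it, the cause was not tested.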

Other observations

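The genes in this paragraph were chosen after their values were seen. Other pigment-cell genes rose: Mlph, a melanosome transport gene, by 1.77 on the log2 scale, Slc24a5, a melanosomal exchanger gene, by 1.07, Pax3, a melanocyte transcription factor gene, by 0.86, and Gpnmb by 1.36, while Slc45a2 had 0.97 (edgeR adjusted p = 0.0516). Slc24a5 shares 39.5% of its exon length with Myef2 on the opposite strand. Kitl, the ligand gene of Kit, had 88.4 ± 25.8 CPM in Cre-positive and 52.5 ± 6.23 CPM in Cre-negative libraries (n = 3 each, edgeR adjusted p = 0.166). The scavenger receptor gene Msr1 rose by 3.10 and Trem2 by 1.52 on the log2 scale, both at low levels (1.63 ± 0.564 and 2.89 ± 0.333 CPM in Cre-positive libraries). Msr1 lay at 0.185 ± 0.0229 CPM in Cre-negative libraries, near the floor of 3 counts, so the size of its fold is uncertain. Ciita, the regulator of class II genes, lay at 0.184, 0.62 and 0 CPM in the Cre-positive libraries, of which 0.62 alone is well above the floor of 3 counts, against 1.49 ± 0.676 CPM (edgeR adjusted p = 0.185). Il34, a growth factor gene for Langerhans cells, had -0.59 (edgeR adjusted p = 0.0920).

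Further genes were also chosen after their values were seen. Rev1, a translesion polymerase gene, rose by 0.86 on the log2 scale (SE 0.12, edgeR adjusted p = 0.0400), and Eif5b on the opposite strand covers 29.1% of its exon length. Rnf169, which binds chromatin at double-strand breaks, rose from 33.6 ± 2.59 to 70.9 ± 5.03 CPM, and Ddias, a damage-induced suppressor of apoptosis, rose by 1.04. Notch1, a receptor gene of keratinocyte differentiation, rose from 298 ± 15.5 to 448 ± 2.96 CPM. The sensor gene Cgas had 0.13 (edgeR adjusted p = 0.685).

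The tests below were chosen after the results were seen, except the counts over other splits of the libraries. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 80 genes and the highest of the others 5, so 1 of 10 splits gave as many; the split with 5 separates the sexes. For gene lists with the preset correlation, the real split gave 17 and the highest of the others also 17, so 2 of 10 splits gave as many. The lowest of the others gave 10, so the number of such list calls does not set the real split apart.

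The rise of p53 target genes was set against the unequal sex of the groups. With sex as a covariate the lower quartile of the members' log2 fold changes stayed above 0 (0.43) and the median was 0.66 against 0.69 without it, which argues against sex as the whole cause, though fewer members passed (7 against 12). The list's call with an estimated correlation ended there (camera adjusted p = 0.111 against 0.0267 without sex). Handling that differed between the groups stays open, because 3 immediate early genes rose too and handling cannot be told apart from genotype here. The genotype itself stays open as well. No sample carried K14-Cre without the floxed alleles, so Cre itself cannot be told apart from the loss of Rnaseh2b.

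The higher melanocyte genes were set against a smaller share of keratinocytes, which would raise every other cell type. The upper quartile of the T cell list was -0.35, below the lower quartile of 0.38 of the melanocyte and Schwann cell list. The fibroblast list had a median of 0.14 and an upper quartile of 0.40, above that lower quartile. The T cell values argue against an equal rise of every other cell type. They cannot exclude a smaller share of keratinocytes, because a separate fall of T cells would give the same outcome. A larger share of melanocytes would raise all 8 markers, and the smallest of their log2 fold changes was 0.42 (Mitf). The markers belong to the list whose rise had been seen, and higher expression per melanocyte would give the same outcome. This test therefore cannot decide for a larger share. Whether a larger share accounts for all of the rise stays open for the markers as a set. A larger share alone would leave the log2 ratios of the 7 other markers to Dct equal between the groups. Their mean differed by 0.16 without overlap, with a pooled SD of 0.10. Single ratios went both ways, from -0.40 for Mitf to 0.76 for Mlana, so this mean does not decide the question. The ratios of 3 of 7 (Tyr, Tyrp1 and Mlana) did not overlap between the groups, where chance gives 10% each. Mlana differed by 0.76 (SD 0.11 in Cre-positive and 0.15 in Cre-negative libraries) and Tyrp1 by 0.63 (SD 0.27 and 0.064). Pmel and Kit, in contrast, differed by 0.02 and -0.01. CD49f sorting does not settle the share of melanocytes, because the gate's contents were not measured here.

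Of the 4 class II genes in the myeloid list, H2-Ab1 fell by edgeR, Cd74 and H2-Aa passed in the same direction when adjusted over the list alone and by DESeq2 over all genes, and H2-Eb1 did not pass by edgeR. With sex as a covariate, Cd74, H2-Aa and H2-Ab1 had -2.58 (SE 0.45), -2.79 (SE 0.48) and -2.31 (SE 0.38). These sizes argue against sex as the whole cause for these 3 genes, which were picked because they were lower. Their sign was largely fixed in advance, since none of the 3 overlapped between the groups and each group held both sexes. With the same covariate H2-Eb1 had -0.50 (SE 0.50) against -0.22 (SE 0.43) without sex. The call for H2-Ab1 ended there (edgeR adjusted p = 0.0770) with a log2 fold change of -2.31 (SE 0.38) against -2.29 (SE 0.32), a larger SE at a similar fold. The shares of myeloid populations and their expression were not separated, and no biological explanation was tested.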
